A study of Mus musculus with 6 samples.

How the data were processed

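RNA of 6 whole skin samples from mouse embryos at embryonic day 17.5 was hybridised to Affymetrix arrays, 3 from Irf6 null and 3 from wild-type embryos. Per the labels, skin was flash frozen, total RNA was column-purified after a proteinase K digestion and labelled with biotin by the manufacturer's single-cycle kit. The deposited values are intensity values per probe set on a linear scale, scaled by the authors so that the mean of each array after trimming 2% at each end is 1500. The summarisation method, its software and any probe-level background step are not given in the sources used here. Group and replicate number of each array were taken from its label, which calls the replicates biological; nothing says how litters were shared, so p-values measure the spread between these samples.

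The table held 45101 probe sets on 6 arrays. Array medians of log2 values differed by 0.24, above the limit of 0.1, so values were quantile normalised between arrays after taking log2(signal + 84.4), where 84.4 is the 20th percentile of all values. Fold changes are therefore on the log2(signal + constant) scale and understate changes of dim genes. After removal of 64 control probe sets, the lowest 40% by mean log2 value were left out without regard to genotype, and 27022 probe sets were kept. No detection calls were used here, so signal over background was judged only by the level.

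Probe sets were named from GEO's platform annotation, updated through the gene identifier to the GRCm38.p6 gene table, which was also used for the order of neighbouring genes; 99.4% of identifiers were found there. Of all probe sets, 34958 carried 1 symbol, 932 several and 9160 were not listed and stay unnamed. No probe set is named Irf6 there. No build is given with the values, so no coordinates are printed. A gene was represented by its brightest kept probe set that names it alone, which gave 12822 genes; 5989 of them had several kept probe sets, and 171 called probe sets had no single name.

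Null was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, genotype as the only term), with a two-sided moderated test and Benjamini-Hochberg adjustment over all 27022 probe sets; a probe set or gene was called at an adjusted p under 0.05. All adjusted p-values for genes come from this limma fit unless a setting is named. With 3 arrays against 3, an exact permutation test of a single gene cannot go below 0.1. The 30 gene lists held 691 genes, of which 542 were measured: cornified envelope, small proline-rich proteins, suprabasal, basal, wound-associated keratins, periderm, barrier lipids, sterol synthesis, proteases, desmosomes and adherens junctions, tight and gap junctions, transcription factors, clefting genes, proliferation, cell cycle exit, hair follicle, NRF2 targets, interferon response, fibroblast, muscle, adipocyte, endothelium, melanocyte, Schwann cell, erythroid, macrophage, mast cell and lymphocyte, cartilage and bone, immediate-early genes, and sex-linked genes. The 29 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. Each list's members were also adjusted over the list alone.

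The lists, the tests, the filter and the rule for naming genes were chosen before the data were examined. The rule named, among called genes whose arrays did not overlap, the 12 with the largest increase and the 12 with the largest decrease that have a proper symbol (names given to uncharacterised clones were passed over), and up to 4 members of each list with the smallest p. Lor, Flg, Ivl, Cdsn, Hrnr, Krt1, Krt10, Krt17, Hbegf, Ereg, Sfn, Tgm1, Tgm3, Rptn, Abca12, Il1b, Cxcl1, Asph, 2310050C09Rik, the Sprr2 and Lce1 genes outside that rule and the genes of the closing observations were named after their values were seen.

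The limma step was tested on simulated data for null against wild type with 27022 probe sets, 50 of them changed at each fold. It recovered 6% of probe sets changed 1.5-fold, 52% changed 2-fold, 88% changed 4-fold and 100% changed 8-fold, with 11 false among 134 calls. Simulated noise was independent between probe sets, and far fewer were changed than the 1408 called here. Recovery in the real comparison can therefore differ. No array had the same values as another. Array quality ratios of 3' to 5' signal were 1.36 to 1.58 for Actb and 0.790 to 0.829 for Gapdh. Alternatives covered the normalisation, the constant, the filter, the variance model, probe set types, the way a gene is represented, a 1.2-fold minimum (treat), the replicate number as a block, each array left out, and, added after the sexes were seen, sex as a term.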

Results

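Skin was taken from mouse embryos at embryonic day 17.5 and profiled on Affymetrix expression arrays, with 3 arrays of skin from Irf6 null embryos and 3 of skin from wild-type embryos. Irf6 encodes interferon regulatory factor 6, a transcription factor of keratinocytes, the cells that build the epidermis. Each array carried biotin-labelled RNA of whole skin, so that epidermis, dermis and any tissue beneath contributed to every value. The labels call the 3 samples of each genotype biological replicates and give a mixed background of 2 inbred strains. Median probe set signal ranged from 383 to 467 over the 6 arrays, and the number of arrays limits the precision of every comparison. Correlation of log2 values across probe sets was 0.958 to 0.980 between arrays of the same genotype and 0.919 to 0.941 between genotypes, where probe sets are not independent replicates.

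The comparison of null with wild-type skin asked which transcripts differ when Irf6 is absent. Late cornified envelope genes, which encode proteins of the outermost dead cell layer, fell furthest in null skin, with Lce1c going from a signal of 74203 ± 4716 in wild type to 73.3 ± 85.0 in null (SD, n = 3 each; log2 difference -9.05, SE 0.30). Keratins of wounded and hyperproliferative epidermis rose furthest, led by Krt6b, which went from 912 ± 304 to 108950 ± 7708 (SD, n = 3 each; log2 difference 6.81, SE 0.22). The calprotectin subunits S100a8 and S100a9, alarmins of stressed keratinocytes and neutrophils, rose by 5.84 and 6.11 on the log2 scale. Krt1 and Krt10, the keratin pair of the suprabasal layers, were not called, at log2 differences of -0.20 and 0.01. Irf6 itself has no named probe set in the annotation used here, so its level was not analysed here and the genotype labels carry no check from the targeted transcript.

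With limma and Benjamini-Hochberg adjustment over 27022 probe sets, 1408 probe sets differed at an adjusted p under 0.05, 757 higher and 651 lower in null skin. Among 12822 genes represented by their brightest probe set, 838 changed, 438 upwards and 400 downwards. Of these, 421 changed at least 2-fold, 190 upwards and 231 downwards, and the largest changes were mostly decreases, with 49 genes at least 8-fold lower against 11 at least 8-fold higher. The 3 null values lay entirely above or below the 3 wild-type values for 4403 genes, which is 34.3% where chance gives 10%. Asph was the only called gene with a further probe set called in the opposite direction. The count of 838 genes ranged from 313 to 453 when any array other than wild-type replicate 1 was left out, and was 923 without that array. Without it, genotype and sex cannot be told apart, since it was the only male wild-type sample by the sex-linked genes described below. Decreases outnumbered increases when any array other than wild-type replicate 1 was left out (121 up and 192 down without null replicate 1) and with sex as a term (118 up and 155 down).

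Sex differed between the groups. Xist, the RNA that silences an X chromosome in females, and the Y-linked genes Eif2s3y, Kdm5d and Uty placed all 3 null arrays and wild-type replicate 1 among males, and wild-type replicates 2 and 3 among females. Mean log2 levels of Xist were 8.46 ± 0.24 in null and 13.14 ± 3.80 in wild-type skin (SD, n = 3 each). Of the 4 sex-linked genes, none was called over all probe sets. Adjusted over the list alone, 3 were called higher and 1 lower. With 1 array left out, 0 to 3 were called higher and 0 to 1 lower over all probe sets. With sex as a term in the limma fit, 273 genes were called, 238 of them among the 838 and in the same direction.

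Among the 12 genes with the largest decreases that have a proper symbol, 9 belonged to the Lce1 family. These fell by 6.86 to 9.05 on the log2 scale. The other genes were Krt23, a type I keratin (-6.96, SE 0.16), Kprp, a proline-rich protein of keratinocytes (-6.68, SE 0.30), and Fmo2, a flavin-containing monooxygenase (-6.37, SE 0.40). The 12 largest increases, chosen likewise, held Krt6b, Krt16 (6.15, SE 0.19), S100a9, Krt6a (5.98, SE 0.20) and S100a8. Il33, an alarmin cytokine of the interleukin-1 family, rose by 4.48 (SE 0.30), Duoxa1, the maturation factor of dual oxidase 1, by 4.12 (SE 0.27), and Dsc2, a desmosomal cadherin, by 4.10 (SE 0.17). Tmem45b (3.99), Serpinb6c (3.22), Slc15a2, a peptide transporter (2.98), and Bcl3, a nuclear member of the IkB family (2.89), completed the increases. Adjusted p-values for these genes ran from 3.36e-06 for Lce1m and Lce1h to 0.0488 for Slc15a2, whose second probe set differed by only 0.15. Null signals of these 9 Lce1 genes ran from 19.4 for Lce1m to 368 for Lce1a1, against the 84.4 added before the logarithm. Signals of Krt23 in null skin (62.5 ± 20.9) and of Tmem45b in wild-type skin (70.2 ± 56.8; SD, n = 3 each) lay below it too, so for these genes the size and rank of the fold depend on that constant. With the lower and the higher constant tried, the difference was -10.03 and -7.86 for Lce1c, -7.80 and -5.83 for Krt23, and 4.90 and 2.93 for Tmem45b.

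Of 30 measured genes of the cornified envelope, the protein shell that replaces the plasma membrane of dead keratinocytes, 20 fell, 3 rose and 7 were not called. Adjusted over the list alone, the counts were again 20 and 3. Decreases included Crct1 (-6.13, SE 0.12) and Cdsn, the gene of corneodesmosin in the junctions of dead cells (-5.12, SE 0.30). Lor, Ivl and Flg, the genes of the major envelope proteins loricrin and involucrin and of filaggrin, fell by 3.06, 3.22 and 1.79. The 3 that rose were Rptn (2.82), the gene of the S100-fused protein repetin, Tchh (1.38), of trichohyalin, and Tgm3 (1.54), a transglutaminase that cross-links such proteins, and 1 increase was called with sex as a term. Tgm1, the main cross-linking enzyme of the epidermal envelope, differed by -0.04 and was not called. The list was lower in null skin by limma's camera test with a preset correlation (median log2 difference -2.90, adjusted p = 4.02e-17), a call lost at adjusted p = 0.342 with an estimated correlation. The small proline-rich proteins, also envelope precursors, went the other way: 5 of 6 measured genes rose, also when adjusted over the list alone, among them Sprr1b (2.63), Sprr1a (2.07) and Sprr2d (1.49), and none fell. With 1 array left out 1 to 4 were called, and 2 with sex as a term. Their camera adjusted p was 1.74e-05, against adjusted p = 0.342 with an estimated correlation. Lce1 and Sprr2 genes are close copies of each other, and 5 of the 11 Lce1 genes were measured by probe sets of types that can bind several transcripts, so values of single members are uncertain.

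Many of these genes lie side by side in the epidermal differentiation complex on chromosome 3, a locus singled out after its values were seen. Of 37 measured genes from S100a1 to Tchh, 19 fell, 9 rose and 9 were not called. All 11 Lce1 genes fell, from -2.24 for Lce1g to -9.05 for Lce1c. Next to Lce1l, 2310050C09Rik fell by 8.14, a clone name that the rule for naming genes had passed over. Between S100a9 and Ivl, Lor fell while Sprr2d, Sprr2j-ps, Sprr2k, Sprr1b and Sprr1a rose, and Sprr2h at 0.14 was not called. At the far end, Flg and Hrnr fell next to Rptn and Tchh, which rose.

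**Figure D1:**
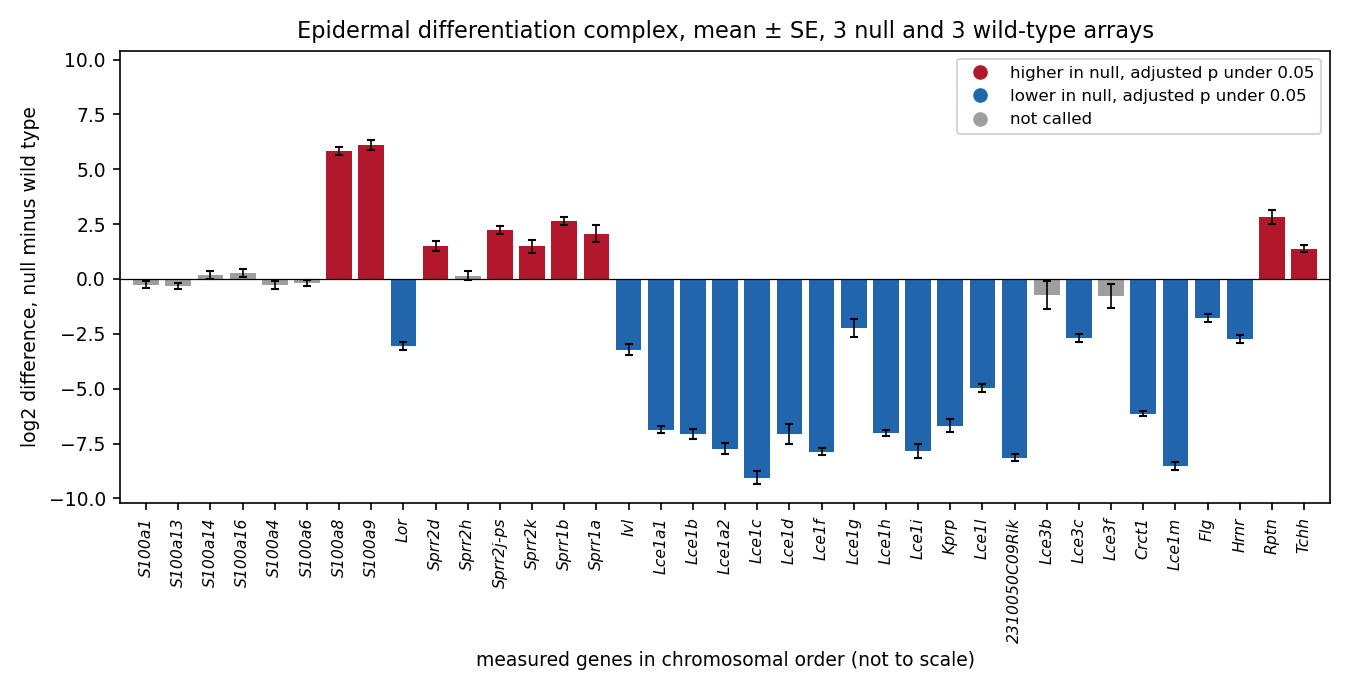
Log2 difference between null and wild-type skin for the 37 measured genes of the epidermal differentiation complex, in chromosomal order and not to scale; bars show the limma estimate and whiskers its SE from 3 null and 3 wild-type arrays. Red bars were called higher, blue bars lower and grey bars not called: 9 genes stand above 0 in red, including S100a8 and S100a9, and 19 below it in blue, including all 11 Lce1 genes.

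Suprabasal differentiation genes split. Of 19 measured, 5 fell, 1 rose and 13 were not called, against 5 and 7 adjusted over the list alone. With 1 array left out, 3 to 5 decreases and 0 to 5 increases were called. Krt77 (-4.58), Krt78 (-3.38) and Krt80 (-1.76), keratins of differentiating epidermis, fell, and Endou, an endoribonuclease, rose by 1.32. The median difference was 0.01, the mean -0.24, and camera's direction was down without a call (adjusted p = 0.579). Krt10 had signals of 136180 ± 7368 in null and 141840 ± 12793 in wild-type skin (SD, n = 3 each), close to the highest value on each array (135722 to 153871), a range in which differences can be compressed.

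Basal keratinocyte genes, which mark the proliferative layer on the basement membrane, had 3 members that rose and 1 that fell among 17 measured (5 and 1 adjusted over the list alone). Trp63, the master transcription factor of stratified epithelium, rose by 0.90, Krt14, the basal keratin, by 0.77 and Col17a1, a hemidesmosome collagen, by 0.70, while Itgb1, the integrin beta 1 subunit, fell by 0.63. The list was called higher (median 0.29, camera adjusted p = 0.0089), with adjusted p = 0.342 with an estimated correlation and adjusted p = 0.0993 with sex as a term. With any array other than wild-type replicate 1 left out, no member was called. Averaged over list members, basal genes differed by 0.26 (SE 0.05), fibroblast genes by -0.26 (SE 0.075) adipocyte genes by -0.44 (SE 0.29), erythroid genes by -0.39 (SE 0.12) and 95 genes of fibroblasts, endothelium, macrophages, mast cells and lymphocytes, melanocytes and Schwann cells by -0.15 (SE 0.07).

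Wound-associated keratins and alarmins held the largest increases. Of 14 measured genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone): beside the 5 genes above, Krt17 rose by 1.44 and Hbegf, an epidermal growth factor receptor ligand, by 1.53, whereas the related ligand Ereg fell by 2.10. The cytokine Il1b (0.54) and the neutrophil chemokine Cxcl1 (0.18) were not called. The list's camera adjusted p was 9.64e-08 with a median of 0.99, and adjusted p = 0.14 with an estimated correlation. The median was 0.50 without null replicate 1 or 2 and 1.57 without wild-type replicate 1, and 2 decreases were called without null replicate 1 or 2. Periderm and simple-epithelium genes had 5 increases and 1 decrease among 12 (6 and 5 adjusted over the list alone) and no camera call (median 0.63, adjusted p = 0.278). Besides Krt6a and Krt17, these were Ripk4, a kinase whose loss gives taut skin (1.29), Grhl3, a grainyhead transcription factor (1.04), and Sfn, the 14-3-3 sigma gene mutated in repeated epilation mice (1.81), with Krt23 as the decrease. Decreases numbered 2 without null replicate 2 and 3 without wild-type replicate 1, and 1 increase was called with sex as a term. Among 13 measured genes whose loss gives clefting or taut skin, 5 rose and none fell, against 5 and 3 adjusted over the list alone. They were Ripk4, Grhl3, Sfn, Trp63 and Tfap2a (0.72), and all 5 also belonged to other lists. With 1 array left out 2 to 6 were called higher, 2 or 3 for any array but wild-type replicate 1, and 0 with sex as a term. The median was -0.11, the mean 0.23 and camera's direction up without a call (adjusted p = 0.302; called by fry at 0.00868).

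**Figure D2:**
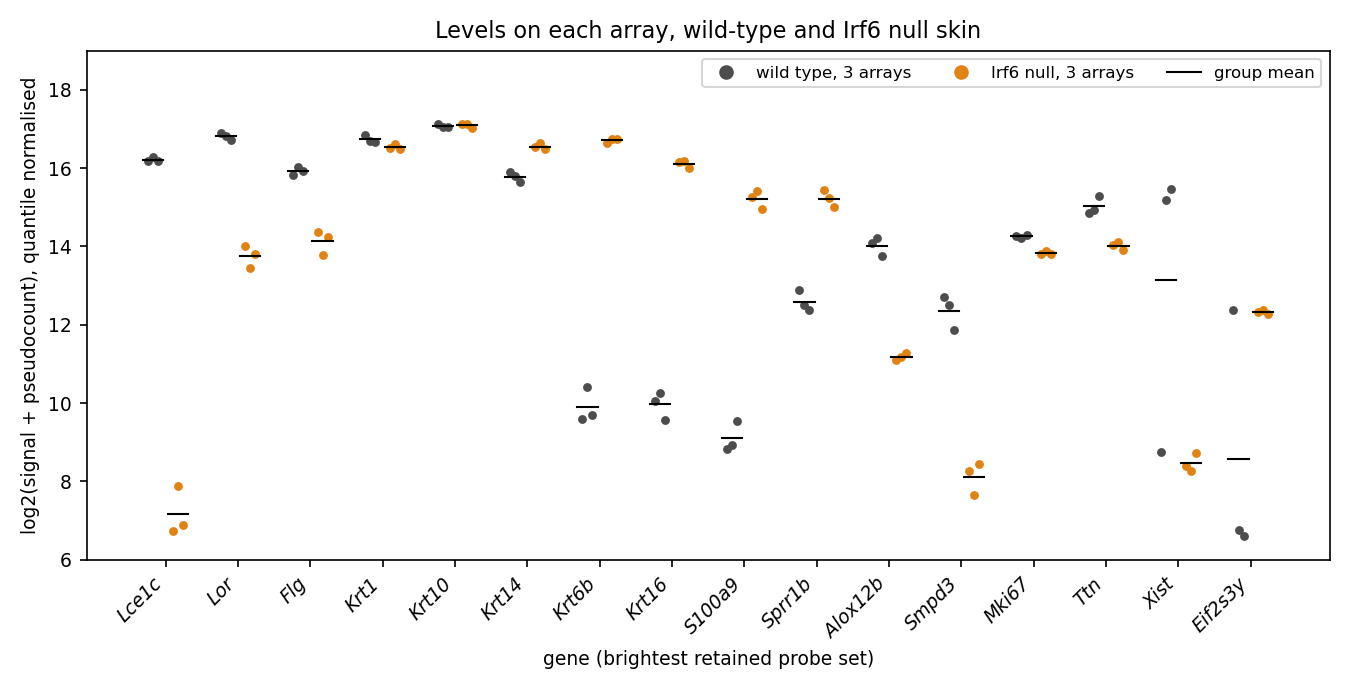
Level of 16 genes on each array as log2 of the signal plus a constant, quantile normalised; grey points are the 3 wild-type arrays, orange points the 3 null arrays, and lines the group means. Krt6b, Krt16, S100a9 and Sprr1b lie higher in null skin, Lce1c, Lor, Flg, Alox12b and Smpd3 lower, Krt10 lies near 17 in both, and Xist and Eif2s3y part wild-type replicate 1 from the other wild-type arrays.

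Of 34 measured genes for the lipids of the stratum corneum, 13 fell, none rose and 21 were not called (16 and 1 adjusted over the list alone). Decreases included Smpd3, a sphingomyelinase (-4.24), Alox12b (-2.84) and Aloxe3 (-2.27), the lipoxygenases whose loss causes ichthyosis, and Elovl1, a fatty acid elongase (-1.46). Abca12, the lipid transporter of lamellar granules, was not called at -0.58. The list's median was -0.56 (camera adjusted p = 2.91e-07; adjusted p = 0.483 with an estimated correlation) and -0.89 with sex as a term. Cholesterol synthesis genes had 3 increases and no decrease among 19 (4 and 1 adjusted over the list alone), Msmo1 (0.92), Sqle (0.91) and Mvd (0.78), enzymes of the pathway. The number of increases was 0 without null replicate 1 or 2 or wild-type replicate 2 or 3, 6 without wild-type replicate 1 and 0 with sex as a term. This list was called higher (median 0.29, camera adjusted p = 0.00173), with adjusted p = 0.502 with an estimated correlation. The call was also lost with sex as a term (adjusted p = 0.0913) and by fry (adjusted p = 0.0796).

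Desquamation proteases and their inhibitors moved both ways, with 8 decreases and 4 increases among 22 (9 and 6 adjusted over the list alone) and no camera call (median -0.35, adjusted p = 0.0983). With 1 array left out, 4 to 8 decreases and 2 to 3 increases were called, 5 and 1 with sex as a term, and 7 and 0 without probe sets that can bind several transcripts, the type that measured Serpinb6c. The median was -0.17 without wild-type replicate 1, -0.58 without wild-type replicate 3 and -0.68 with sex as a term. Serpina12, a serpin (-3.04), Klk7, a kallikrein that sheds corneocytes (-2.38), and Asprv1, a protease that processes filaggrin (-1.34), fell, and Serpinb6c rose. Without wild-type replicate 3 the list was called lower, at adjusted p = 0.014, and with sex as a term at adjusted p = 0.00847. Desmosome and adherens junction genes had 6 increases and no decrease among 19 (8 and none adjusted over the list alone). Dsc2, Jup, the plakoglobin gene (1.01), Pkp3, a plakophilin (0.97), and Ctnnd1, the p120 catenin gene (0.77), were among them. With sex as a term 1 member was called higher. The list was called higher (median 0.46, camera adjusted p = 2.95e-07), with adjusted p = 0.357 with an estimated correlation and a median of 0.28 with sex as a term, and 1 to 3 members were called when any array other than wild-type replicate 1 was left out. Tight and gap junction genes had 5 increases and 3 decreases among 15 (5 and 4 adjusted over the list alone; median 0.10, camera adjusted p = 0.427), including the connexin gene Gjb2 (2.27) and the claudin Cldn1 (1.18) upwards, and the claudin Cldn23 (-1.81) and the cingulin gene Cgn (-1.07) downwards. Between 2 and 4 increases and 1 and 3 decreases were called with 1 array left out, and 1 of each with sex as a term. The median ran from -0.09 without null replicate 3 to 0.21 without null replicate 2.

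Of 36 transcription and signalling regulators of epidermal differentiation, 7 rose and 3 fell (14 and 4 adjusted over the list alone). Hopx, a homeodomain-only protein of terminal differentiation, fell by 2.09 and Rora, a nuclear receptor, by 1.39, as did Prdm1, the Blimp1 repressor gene (adjusted p = 0.00589), while Grhl3 rose. The 7 increases became 1 to 4 when any array other than wild-type replicate 1 was left out and 0 with sex as a term, whereas 3 decreases were called whichever array was left out. The list was called higher (median 0.35, camera adjusted p = 0.00225), with adjusted p = 0.502 with an estimated correlation. The call was also lost with sex as a term (median 0.16, adjusted p = 0.264) and by fry (adjusted p = 0.0536), and the median was 0.53 without wild-type replicate 1 and 0.21 without wild-type replicate 3. Of 25 hair follicle genes, 3 rose and 4 fell (5 and 6 adjusted over the list alone). Tchh, Foxq1 (1.73) and Foxn1 (1.33), forkhead factors of the hair shaft, rose and Gli1, a Hedgehog target, fell by 0.68; the median was -0.02, the mean 0.03 and the camera direction down without a call (adjusted p = 0.898). No decrease was called when any array other than wild-type replicate 1 was left out, and 1 or 2 increases were; with sex as a term neither was.

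Of 41 genes of S phase and mitosis, only Rrm2, a ribonucleotide reductase subunit, was called, falling by 0.69, both over all probe sets and adjusted over the list alone, and 40 of the 41 had a negative log2 difference. Mki67, the gene of the Ki-67 antigen, had a difference of -0.42 and Ube2c one of -0.44, neither called. The call of Rrm2 was lost when any array other than wild-type replicate 1 was left out. The list was called lower (median -0.26, camera adjusted p = 9.64e-08; adjusted p = 0.342 with an estimated correlation). The cell cycle exit list holds cyclin-dependent kinase inhibitors and p53 target genes, but also D cyclins and genes of the retinoblastoma family. It had 3 increases among 18 and no decrease (3 and 1 adjusted over the list alone), with the D cyclin Ccnd2 not called at -0.56. The increases were Cdkn2b (adjusted p = 0.0245), Trp53inp1 (1.03) and Phlda3 (0.87). None was called without null replicate 1 or 3 or with sex as a term, and 1 without null replicate 2. The median was -0.11, the mean 0.07 and camera's direction down without a call (adjusted p = 0.634).

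Targets of the oxidative stress factor NRF2 had 6 increases and 3 decreases among 21 (9 and 4 adjusted over the list alone). Gsta4, a glutathione transferase (1.77), and Akr1b8, an aldo-keto reductase (1.45), rose; Txnrd1, thioredoxin reductase (-1.55), and Hmox1, heme oxygenase (-1.57), fell. With 1 array left out, 2 to 5 increases and 2 to 3 decreases were called, and 2 of each with sex as a term. The list was called higher (median 0.37, camera adjusted p = 0.0262), with adjusted p = 0.483 with an estimated correlation. The call was also lost with sex as a term (median 0.20, adjusted p = 0.364) and without null replicate 1 (0.0598), wild-type replicate 2 (0.0601) or wild-type replicate 3 (0.0997). Interferon response genes had 3 increases and no decrease among 24 (4 and none adjusted over the list alone; median 0.18, camera adjusted p = 0.101). These were Gbp3, a guanylate-binding protein (1.04), Irf9 (0.73) and H2-D1, a class I histocompatibility gene (0.57), whose call did not hold without probe sets that can bind several transcripts (-0.25, adjusted p = 0.498). At most 1 member was called when any array was left out and none without those probe sets, and the median was 0.10 without null replicate 1. The list was called higher without null replicate 2 (adjusted p = 0.0436) or null replicate 3 (0.0387). Immediate-early and heat-shock genes, which react to handling, had 2 increases, Fos (1.42) and Hspa1a (1.32), and 1 decrease, Egr2 (-1.95), among 22 (5 and 3 adjusted over the list alone); the median was -0.13, the mean 0.00 and the camera adjusted p = 0.853. Between 1 and 4 increases and 0 and 2 decreases were called with 1 array left out.

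All 27 skeletal muscle genes had negative differences and 9 fell (22 adjusted over the list alone). Among them were Ttn, the titin gene (-1.01), Myh1, a myosin heavy chain (-0.98), and the troponins Tnnt1 (-0.88) and Tnnc1 (-0.80). Of 6 kept Ttn probe sets 1 was called, and their differences ran from -1.01 to -0.09. The muscle list was called lower (median -0.54, camera adjusted p = 2.53e-12, and adjusted p = 0.357 with an estimated correlation). Between 0 and 8 of its members were called when 1 array was left out. With sex as a term 0 members were called, the genotype then resting on 1 male wild-type array, while the list's camera call was kept. Dermal fibroblast genes had 1 decrease among 26, Mfap5 (-1.05), also adjusted over the list alone, with 25 negative differences (median -0.22, camera adjusted p = 6.91e-05; adjusted p = 0.502 with an estimated correlation). Adipocyte genes had 2 decreases among 12 (5 decreases and 1 increase adjusted over the list alone), the lipases Lipe (-1.84) and Lpl (-0.57), with a median of -0.53 (camera adjusted p = 0.014; adjusted p = 0.515 with an estimated correlation); the call was lost without wild-type replicate 3 (median -0.26, adjusted p = 0.0997; median -0.34 without null replicate 2) and by fry (adjusted p = 0.11), and 1 decrease was called whichever array was left out. No fibroblast gene was called without null replicate 1 or 2 or wild-type replicate 2 or 3, and the fibroblast median was -0.13 with sex as a term.

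Endothelial genes had 1 decrease among 17, Robo4, a receptor that stabilises vessels (-0.67; 1 decrease and 1 increase adjusted over the list alone; camera adjusted p = 0.232). Schwann cell and nerve genes had 1 increase, the neuregulin receptor Erbb3 (0.70), and 1 decrease, Egr2, among 11, also adjusted over the list alone (camera adjusted p = 0.302). Each of these 3 calls was lost when any 1 null array was left out. No member was called over all probe sets among 12 melanocyte genes (camera adjusted p = 0.399), 7 erythroid genes (0.101), 20 macrophage and dendritic cell genes (0.898), 12 mast cell and lymphocyte genes (0.082) or 10 cartilage and bone genes (0.634). Adjusted over the list alone, 1 erythroid gene, Alas2, the heme synthesis enzyme (-0.90), was called and none of the other 4 lists had a call. The macrophage median was -0.03 with a mean of 0.01. Medians of the macrophage, suprabasal, clefting, hair follicle, junction (tight and gap) and cartilage and bone lists took both signs as single arrays were left out. Without wild-type replicate 1 the erythroid list (adjusted p = 0.0408) and the mast cell list (0.0213) were called lower, and the mast cell list also without null replicate 3 (0.0481).

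**Figure D3:**
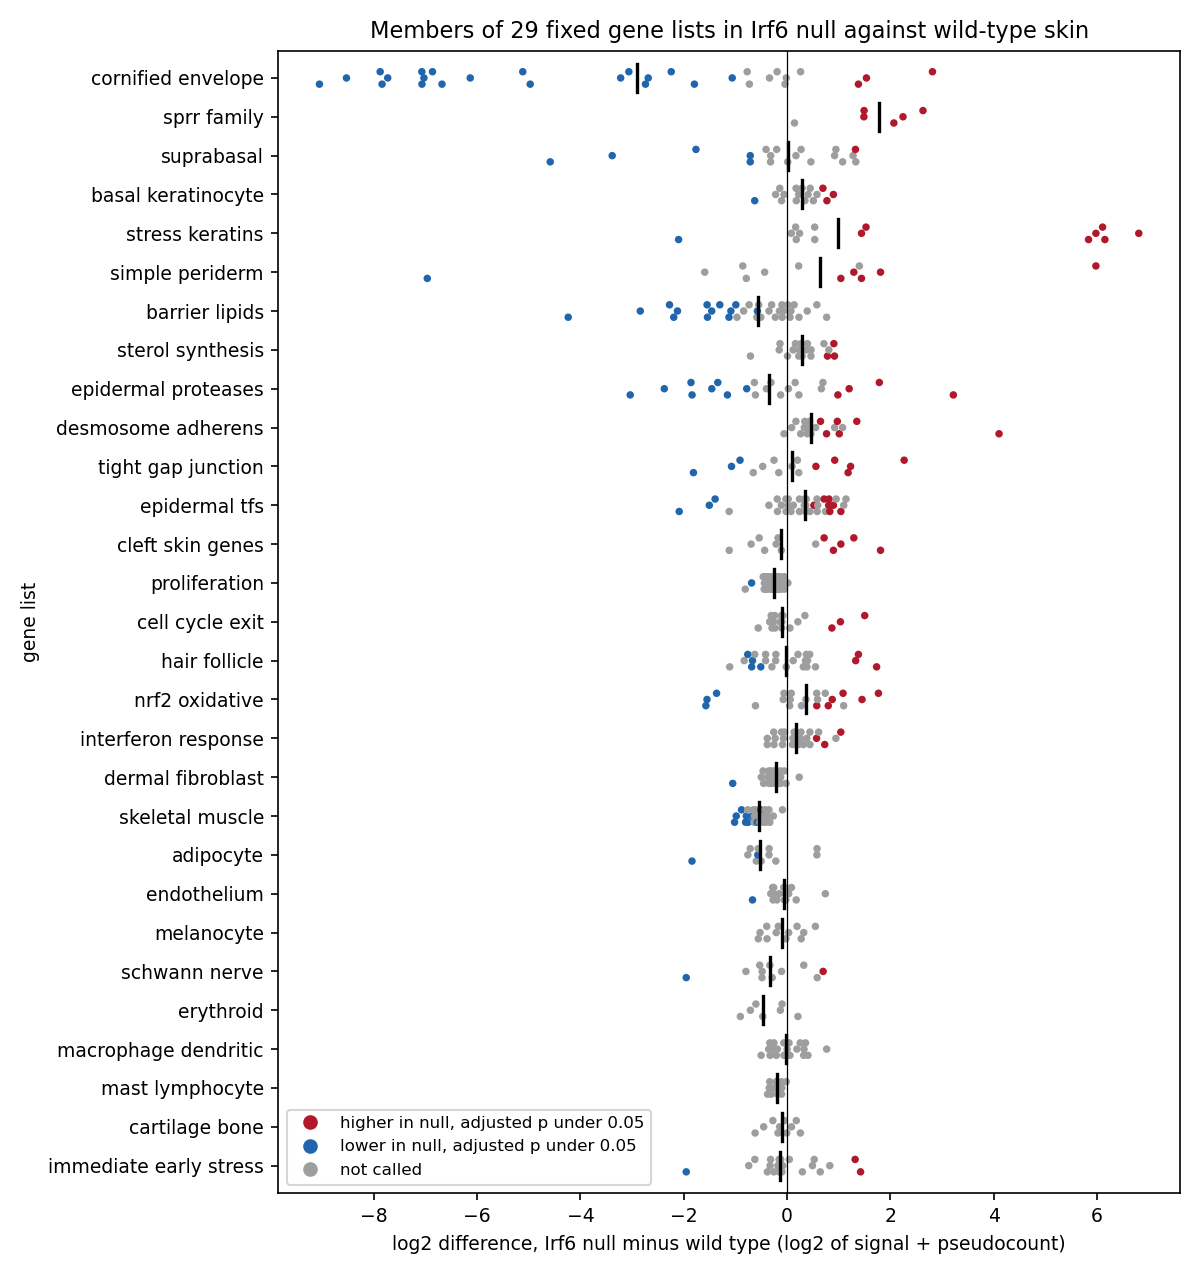
Log2 difference between null and wild-type skin for each measured member of 29 gene lists; red points were called higher, blue points lower and grey points not called, and black bars are list medians. Cornified envelope genes reach -9.05 with a median of -2.90, the Sprr family has a median of 1.78, and the 27 skeletal muscle genes all lie below 0.

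Of the 29 lists tested, camera with the preset correlation called 13, with 7 higher and 6 lower. With the correlation estimated from the 6 arrays it called 0, with 2 lists at an unadjusted p under 0.05. In that setting its test also rests on the 4 residual degrees of freedom of the fit. For wound-associated keratins the estimated correlation was 0.0109, near the preset 0.01, yet camera's adjusted p went from 9.64e-08 to 0.14. A call lost in that setting therefore does not by itself show that the members were correlated. With sex as a term camera called 3 higher and 7 lower. Rotation testing with fry, which asks whether a list's genes move on balance in a single direction, called 11.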

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

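Sex as a term was the only setting chosen after seeing the data. The 1408 called probe sets, 838 called genes and 421 genes changed at least 2-fold depended on the fit as follows, and the cause was not tested unless named. With the replicate number as a block, 521 probe sets and 342 genes were called. Deviations of same-numbered arrays correlated at 0.07, -0.07 and 0.08, and 1 of 3 null arrays correlated best with its own number. No pairing by number was seen, but 3 arrays per group are too few to exclude it. Without a filter the counts were 639 and 397, with the lowest 60% left out 2156 and 1343, with a variance trend 2591 and 1592, with a robust trend 2622 and 1610, without probe set types that can bind several transcripts 781 and 553 (fewer were tested), and against a 1.2-fold minimum, a stricter question, 585 and 386. With sex as a term they were 410 and 273, and all 273 genes were changed at least 2-fold, against 421. Leaving out 1 array gave 478 to 1748 probe sets, 313 to 923 genes and 292 to 470 genes changed at least 2-fold. Each array except wild-type replicate 1 lowered the first pair of counts by over 1.5 times. The highest counts came without that array, where male null arrays faced female wild-type arrays only. Of 29 lists, 13 were called, 0 with an estimated correlation, 11 by fry, 10 with sex as a term and 12 to 15 without 1 array. Over 435 comparisons of lists, 388 kept direction and side of the threshold, 24 lost the call, 8 gained it and 15 uncalled ones changed sign. Over 2385 comparisons of 128 named genes, 2001 kept both, 319 lost and 56 gained the call, 8 uncalled ones changed sign, and H2-D1 turned to -0.25 without probe set types that can bind several transcripts, where another probe set stands for the gene. No scaling moved the median of all probe sets by over 0.1. Each scaling brings the arrays to a common level, so a shift of all genes together was not tested. Dim signals limit the folds of some Lce1 genes in null skin. Called genes that were higher and lower numbered 438 and 400, but 153 and 189 with the block, 176 and 221 without a filter, 803 and 807 with a robust trend, 173 and 213 against the 1.2-fold minimum and 118 and 155 with sex as a term.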

Other observations

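The tests of the epidermal share of the sample, of the 40 Mb window around Irf6, of single lists over the splits of the arrays, the sex term, and the choice of the cytokine and growth factor genes below were made only after the results were seen.

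Among genes of the interleukin-1 family, Il33 rose by 4.48 on the log2 scale, whereas Il18 (-3.44, SE 0.16), Il1f6 (-2.66, SE 0.37), Il1f5, the receptor antagonist of that branch (-2.46, SE 0.28), and Il1f8 (-1.87, SE 0.28) fell, as did the decoy receptor Il1r2 (-2.54, SE 0.22). Il1b (0.54), Il1rn (0.54), Il1f9 (-0.37) and Il1f10 (-0.83) were not called. Among ligands of the epidermal growth factor receptor, Epgn (2.21, SE 0.16) and Hbegf (1.53, SE 0.22) rose, and Btc (-2.91, SE 0.20) and Ereg (-2.10, SE 0.14) fell, while Egf (-0.08) and Tgfa (-0.48) were not called. Il4ra (1.87, SE 0.14) and Il13ra1 (1.88, SE 0.13), the chains of the interleukin-4 and interleukin-13 receptor, rose together with Il20ra (2.19, SE 0.22) and Socs3 (1.67, SE 0.19), an inhibitor of cytokine signalling. Duox1, a hydrogen peroxide generating oxidase, rose by 2.02 (SE 0.18) beside its partner Duoxa1, and the glycerol channel Aqp3 by 2.33 (SE 0.34). All genes said here to have risen or fallen passed an adjusted p of 0.05 in the limma fit. Genes with interleukin symbols were not called as a family (39 genes, camera adjusted p = 0.832), families named by the Socs and Aqp symbols were not called either (adjusted p = 0.512 and 0.785), and the other groups of genes here were not tested.

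Too few splits of the 6 arrays exist, 10, for a share under 0.05. Every split other than null against wild type mixes the genotypes on both sides. Genotype differences then widen the spread and push the counts of probe sets and genes towards 0, so those counts are no chance level. The real split gave 1408 probe sets, 838 genes and 421 genes changed at least 2-fold, against 0 in the highest other split by limma for each of them, so that 1 of the 10 splits reached each count; the other splits had 569 to 2030 probe sets at an unadjusted p under 0.05, and the real split 6116. For lists the highest other split, null replicates 1 and 2 with wild-type replicate 1 against the rest, also called 13 by camera with the preset correlation, so that 2 of the 10 splits reached that count. Of the 13 called lists, 9 had no other split with as small an adjusted p, and 4, sterol synthesis, transcription factors, NRF2 targets and adipocytes, did. Every other split still called lists, from 3 to 13 of them. Each of the 13 lists was also called in 2 to 6 of the 9 other splits, muscle and proliferation in 6, cornified envelope and barrier lipids in 5. These splits mix the genotypes too, so this is no chance level either.

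Xist and the Y-linked genes put the null embryos and wild-type replicate 1 among males and the other 2 wild-type embryos among females, so sex is a candidate explanation for differences between the groups. That 0 of 4 sex-linked genes were called does not argue against it, because both sexes within the wild-type group inflate its spread. With sex as a term, the median ratio of adjusted to unadjusted log2 difference over the 838 called genes was 0.988 and all 838 kept their sign. Genes in which wild-type replicate 1 departs from the other wild-type arrays are seldom called, for the same reason. Choosing called genes thus favoured a ratio near 1 in advance, so these values do not decide whether sex contributes. Over these genes the median SE grew from 0.149 to 0.192 and the median size became 0.977, the genotype then resting on 1 male wild-type array. The sex term, male minus female, was -6.58 for Xist and 5.71 for Eif2s3y on the log2 scale and rests on that array too. An effect of sex on other genes stays open.

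If the null allele carries DNA of another strain than the wild-type allele, neighbours of Irf6 could differ by strain and not by loss of Irf6. Within 20 Mb on either side, 9 of 109 measured genes were called (8.26%) against 827 of 12692 elsewhere (6.52%), an odds ratio of 1.29 (95% interval 0.572 to 2.56, Fisher's exact p = 0.434). The interval holds both no excess and a 2-fold one, so strain and genotype cannot be told apart for these 9 genes, and the labels do not say from which strain the allele came. Within 40 Mb the odds ratio was 1.78 (95% interval 1.12 to 2.72, Fisher's exact p = 0.0101, 0.0505 adjusted over 5 windows). The 9 genes include Ifi202b, an interferon-inducible gene known to differ between inbred strains (2.41, SE 0.30), and Mir205hg, the host gene of a keratinocyte microRNA (1.33, SE 0.21).

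Skeletal muscle genes were lower in null skin, by 0.58 on average on the log2 scale (-0.58, SE 0.10). A larger share of epidermis in the null samples would alone lower every non-epidermal tissue alike. Muscle fell further than 95 genes of 6 other non-epidermal types (-0.42, SE 0.08) and than all 124 genes of 9 such types (-0.38, SE 0.07). Those sets do not decide it: they hold genes that rose, such as Erbb3 (0.70), and their types ranged from 0.01 for macrophages to -0.44 for adipocytes. Muscle also fell further than fibroblast genes (-0.31, SE 0.06), and an equal lowering of both, measured alike, would not give that gap. Fibroblast genes were brighter, however, at mean log2 levels of 14.56 to 14.98 per array against 13.39 to 14.17 for muscle. Compression of bright signals could narrow their difference and was not tested, so this gap does not decide it either. No single array carried the muscle decrease: the 3 null scores lay below the 3 wild-type scores, and at least 0.838 of the difference was left without any 1 array. Choosing a called list favoured such a separation in advance. Muscle caught in several wild-type dissections is not covered, where scores were 13.85, 13.92 and 14.17 against 13.39 to 13.43 in null. Basal keratinocyte genes were higher (0.26, SE 0.05) and fibroblast genes lower (-0.26, SE 0.075), as a larger share of epidermis would give. That share stays open for these genes and for some or all of the muscle decrease. Sex was not taken out of these scores. Wild-type replicate 1, the only male wild-type sample, lay nearest the null arrays in the basal, fibroblast and muscle scores. Its basal score was 12.99, against 12.89 and 12.82 in the other wild-type arrays and 13.15 to 13.18 in null. Its fibroblast score was 14.76, against 14.89 and 14.98, and 14.56 to 14.69 in null. Muscle was not set apart from adipocyte (-0.14, SE 0.24), erythroid (-0.19, SE 0.12) or Schwann cell genes (-0.27, SE 0.17), so how deep the skin was cut in the groups as a whole also stays open, as does the muscle layer itself, neither of them tested.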
